A study of Homo sapiens with 12 samples.

How the data were processed

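ATAC-seq was performed on 6 libraries, 3 of ARPE-19 and 3 of H7, and each sample had 1 peak list. The 6 samples of 4C in the same series were not analysed here. Per the submitters' processing notes, the genome build was hg19 and MACS2 and bedtools were used, with no versions. The aligner, the treatment of duplicate reads and mitochondrial reads, and any shift of reads for the transposase were not given in the sources used here. If reads were not shifted to the insertion site, summits would move by a few bases, and the lists hold peaks on mitochondrial DNA, so such reads were kept at peak calling. Peaks were called per library and not on pooled samples, which allows replicates to be compared by overlap.

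The deposited lists give for each peak a position, a score, a fold enrichment at the summit, and -log10 values of p and q. In at least 99.988% of the rows of each list the deposited score was 10 times the -log10 q of the peak as a whole number. The deposited fold enrichment is a ratio of the reads at the summit to the local background of the same library, as the authors' peak caller gave it. The deposited -log10 p and -log10 q come from the same test within a library, and no peak in the lists had a q above 0.05. These are the authors' own values per peak, and they were used here to describe, rank or filter peaks within a list. They also served for a common threshold on -log10 p, and to recover reads and backgrounds that were compared between libraries.

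Positions are given 1-based on hg19. Gene models or sequence of hg19 were not used here. The table of genes at hand was of GRCh38, and on 13 of 22 autosomes the last peak lay past the last gene of that table, so no peak was assigned to a gene. The planned results on promoters, the TERT promoter, the TERT locus, gene lists and sequence motifs were therefore not run. The rule for named regions was fixed before the data were examined. For each direction it takes the 3 regions with the highest mean within-library percentile of -log10 q over the 3 libraries that have the region. Regions on sex chromosomes were not named. The regions called in all 6 libraries, the window on chromosome 5 and the autosomes were described in addition, and those were chosen after the lists had been seen.

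The lists were merged into regions wherever peaks of any libraries overlapped by at least 1 base. A region was H7-only with a peak in 3 of 3 H7 and 0 of 3 ARPE-19 libraries, and ARPE-19-only the other way. Peak numbers and covered bases were compared on the log2 scale by an exact two-sided permutation test over 20 assignments of the 6 libraries, whose smallest p is 0.1. Regions of one line were compared between each autosome and the others by Fisher's exact test with Benjamini-Hochberg adjustment over 22 autosomes. The alternatives were a -log10 q of at least 5, the same number of peaks from every library (the 8622 with the highest -log10 p), looser definitions of the regions of one line, overlap by at least 50% of the bases, and leaving out each library in turn. Others were chosen after the lists had been seen, namely autosomes only, one threshold on -log10 p (4.31) for all libraries, the same number of peaks for the overlap between libraries, and removal of peaks whose local background was over 5 times that of the library.

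The reads behind each peak were recovered as follows. In MACS2 the fold is the summit pileup plus 1 over the background plus 1, and p is the upper tail of a Poisson distribution with that background. A whole number of summit reads and a background were solved for each peak from its fold and its -log10 p. They met the deposited -log10 p within 0.001 for 100% of the nuclear peaks of each library. The most frequent background, which was also the lowest, was taken as the genome-wide background of the library. It is proportional to the number of reads times the length to which the caller extended them, so it gives relative and not absolute depth. At that background, the fewest summit reads of a called peak were 4 in the ARPE-19 libraries and 5 to 6 in the H7 libraries, which sets the smallest signal that could be called. Counting error alone limits a peak of 4 reads, and reads may include duplicates.

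The steps were tested on simulated data. For the comparison of H7 with ARPE-19, lists were simulated from 84664 regions with 200 planted H7-only and 200 planted ARPE-19-only regions, and 100% of each were recovered. Planted regions had overlapping peaks in all 3 libraries of their line, so their recovery follows by construction. This checks the steps, and not how many true regions are missed in lists of unequal length. For the recovery of reads, 99.94% of 5000 simulated peaks gave the right number. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.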

Results

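Chromatin accessibility was measured by ATAC-seq in 2 human cell lines, ARPE-19 and H7. ARPE-19 is a spontaneously arising line of retinal pigment epithelial cells, and H7 is a line of embryonic stem cells. In ATAC-seq the Tn5 transposase inserts sequencing adapters into open chromatin, and a peak marks a stretch where insertions pile up over the background. Each line had 3 libraries made from 500000 cells each, with 1 peak list per library. The series also holds 6 samples of circular chromosome conformation capture (4C) with a viewpoint at the gene of the telomerase reverse transcriptase, which were not analysed here. The title of the series concerns expression of that gene, TERT, during development, and the design text names accessibility and chromatin contacts. The accessibility data therefore ask which regions are open in one line and not in the other.

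The lists give no read totals. The genome-wide background that the peak caller used could be recovered from each list and serves as a measure of relative depth. It was 0.483, 0.458 and 0.425 expected reads per position in ARPE-19 replicates 1, 2 and 3. It was 0.653, 0.592 and 0.633 in H7 replicates 1, 2 and 3, so that the mean of the H7 libraries was 1.38-fold higher (exact permutation test, two-sided p = 0.1, n = 3 per line). With 3 libraries against 3, a p of 0.1 is the smallest that this test can give, and no comparison of library values below can pass a threshold of 0.05. The labels call the libraries triplicates without saying whether they came from separate cultures, so the p-values measure only the spread between these libraries.

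Far more open regions were called in the retinal pigment epithelial line than in the stem cells. The ARPE-19 lists held 44456, 40110 and 48460 peaks, with a mean of 44342 ± 4176 (SD, n = 3). The H7 lists held 15351, 13707 and 8622 peaks, with a mean of 12560 ± 3508 (SD, n = 3). The ARPE-19 mean was 3.53-fold higher, and the log2 difference of H7 from ARPE-19 was -1.86 (SE 0.27, exact permutation p = 0.1). Every ARPE-19 list was longer than every H7 list. The peaks covered 13.7 ± 1.62 Mb in ARPE-19 and 3.24 ± 0.94 Mb in H7 (SD, n = 3), a log2 difference of -2.12 (SE 0.28, exact permutation p = 0.1). When only the 8622 strongest peaks of each library were kept, the log2 difference in covered bases was -0.63. ARPE-19 peaks were also wider, with a median width of 269 ± 7.09 bases against 226 ± 2.89 bases in H7 (SD, n = 3, exact permutation p = 0.1).

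**Figure D1:**
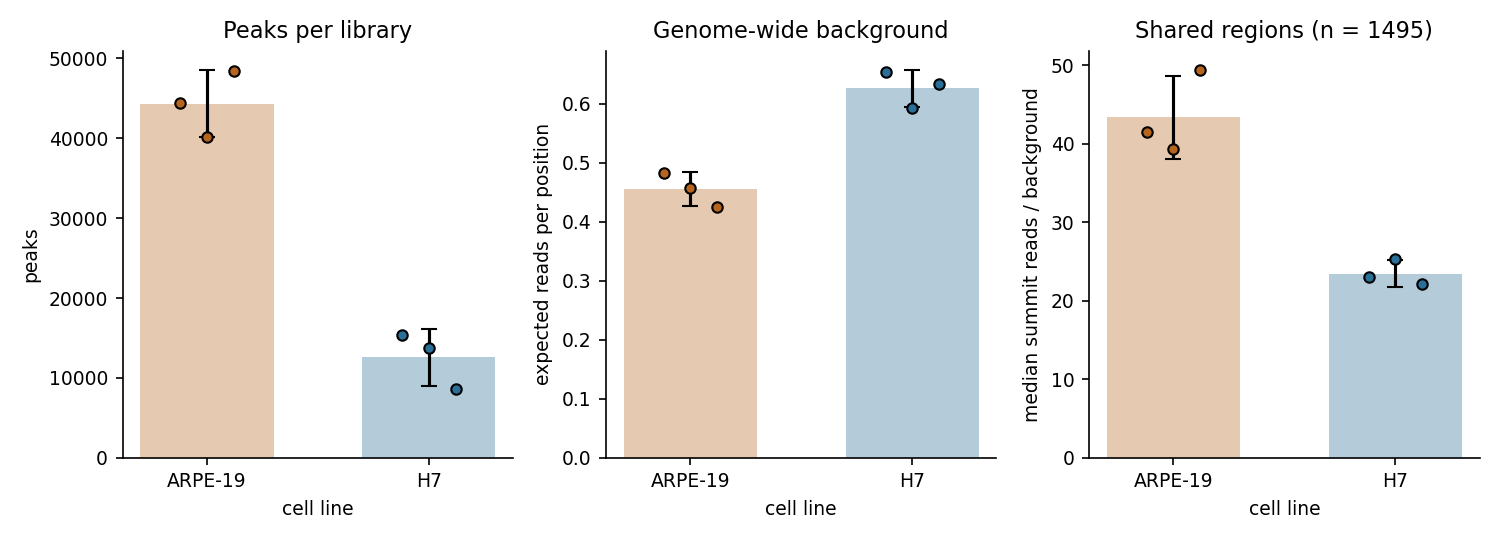
Bars give the mean and error bars the SD of 3 libraries per cell line, and points give the libraries in the order of replicates 1, 2 and 3; the panels plot peaks per library, the genome-wide background in expected reads per position, and the median number of summit reads over background at 1495 autosomal regions called in all 6 libraries. H7 had fewer peaks (12560 against 44342), a higher background (0.626 against 0.455) and a lower summit over background at shared regions (23.5 against 43.4).

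Merging the 6 lists gave 84664 regions. ARPE-19-only regions, with a peak in 3 of 3 ARPE-19 libraries and in 0 of 3 H7 libraries, numbered 22042. H7-only regions, defined the other way, numbered 1537, a ratio of 14.3 to 1. Another 1543 regions had a peak in all 6 libraries, a count that was 705 with a -log10 q of at least 5, 551 with the same number of peaks from every library and 388 with peaks over at least 50% of the merged region. Of the 3401 regions called in all 3 H7 libraries, 54.8% also had a peak in at least 1 ARPE-19 library, while 17.3% of the 26664 regions called in all 3 ARPE-19 libraries had one in H7. The excess of ARPE-19-only regions was smaller when the same number of peaks was taken from every library, with 4012 ARPE-19-only and 1840 H7-only regions, a ratio of 2.18. The shares with a peak in the other line were then 34.2% of the 2795 regions called in all 3 H7 libraries and 19.8% of the 5003 called in all 3 ARPE-19 libraries. At equal list length, fewer regions were thus called in all 3 libraries of H7 before the other line was considered. Without H7 replicate 3, the shortest list, there were 3087 H7-only regions and the ratio was 7.27. The ratio was 27.2 with a -log10 q of at least 5, with 605 H7-only regions. With a peak in at least 2 of 3 libraries of one line it was 7.71 against 0 of 3 of the other line and 7.53 against at most 1 of 3.

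**Figure D2:**
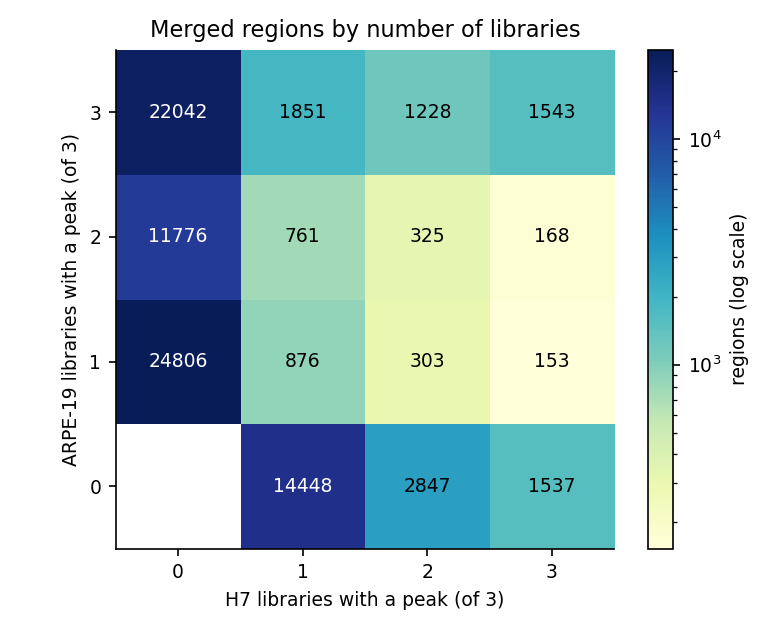
Each square gives the number of merged regions by how many of 3 ARPE-19 libraries (vertical axis) and how many of 3 H7 libraries (horizontal axis) had a peak, coloured on a log scale. ARPE-19-only regions (22042, upper left) outnumber H7-only regions (1537, lower right), and 14448 regions were called in a single H7 library and in no ARPE-19 library.

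The strongest regions of each class were ranked by the within-library percentile of their -log10 q, with positions on hg19 and without sex chromosomes. The strongest H7-only region lay on chromosome 5 from 134262521 to 134262774, with 212 to 233 reads at the summit in the 3 H7 libraries. Its local background was also high, at 17.5 times the genome-wide background, where the median H7-only region had 1.62 times. Whether reads from nuclear copies of mitochondrial DNA or from other multicopy sequence add to it was not tested. The next H7-only regions lay on chromosome 13 from 78427780 to 78428199, with 29 to 44 summit reads, and on chromosome 2 from 15399504 to 15400009, with 27 to 36. The strongest ARPE-19-only region lay on chromosome 1 from 165085778 to 165086472 and had 104 to 143 summit reads. It was followed by a region on chromosome 8 from 68604909 to 68605582, with 85 to 107 summit reads, and one on chromosome 2 from 106593731 to 106594243, with 69 to 80. When peaks with a local background over 5 times that of their library were removed, the first H7-only region and the first 2 ARPE-19-only regions were lost, and the third was kept in 1 library. The local background can hold reads of the peak itself, so this removal can fall on strong peaks by construction. The loss alone does not make a region doubtful. A region with a peak in 3 libraries of one line and in none of the other has an exact p of 0.1. Whether these regions lie in genes or promoters was not analysed here, because gene models on hg19 were not used.

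The strength and width of peaks differed between classes of regions within a list, and the demand for a call in several lists selects strong peaks by construction. Peaks in the 1543 regions of all 6 libraries had a median width of 428 ± 22.4 bases in ARPE-19 and 297 ± 15.7 bases in H7 (SD, n = 3). Their median strength stood at the 82.0th percentile of the ARPE-19 lists and of the H7 lists, which differ in length. ARPE-19-only peaks had a median width of 317 ± 17.5 bases and stood at the 66.9th percentile of their lists. H7-only peaks had a median width of 286 ± 18.7 bases and stood at the 74.5th percentile. In each of the 3 H7 libraries their median width was below that of peaks in shared regions, with 303, 289 and 266 bases against 309, 302 and 279. The region in all 6 libraries with the highest rank lay on chromosome 1 from 121484430 to 121485424, with 300 to 749 summit reads over a local background of 15.4 to 34.9 reads. It and the next 2 regions of this class were lost when peaks with a local background over 5 times that of their library were removed. Here too the local background can hold reads of the peaks themselves.

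Replicate lists overlapped more within ARPE-19 than within H7, and a longer list is overlapped more often by construction. On average 70.5% of the peaks of an ARPE-19 library overlapped a peak of another ARPE-19 library (range 64.2% to 77.7% over 6 ordered pairs), against 41.1% within H7 (29.5% to 52.6% over 6 ordered pairs). Between the lines, 29.5% of H7 peaks overlapped a peak of an ARPE-19 library and 8.06% of ARPE-19 peaks overlapped one of an H7 library. The Jaccard index of covered bases averaged 44.9% within ARPE-19, 20.4% within H7 and 5.19% between the lines. Among the 1000 strongest peaks of a library, 99.97% were found in another ARPE-19 list and 87.8% in another H7 list. Of the 1000 strongest H7 peaks, 55.1% overlapped an ARPE-19 peak, and of the 1000 strongest ARPE-19 peaks, 21.1% overlapped an H7 peak. With the same number of peaks from every library, the mean overlap was 70.0% within ARPE-19 and 45.9% within H7, and between the lines it was 13.4% of H7 peaks and 13.3% of ARPE-19 peaks. Against these lists of equal length, 35.8% of the 1000 strongest H7 peaks overlapped an ARPE-19 peak and 19.9% of the 1000 strongest ARPE-19 peaks an H7 peak. These overlaps were not tested.

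The distal short arm of chromosome 5, the arm that carries TERT, was examined because TERT is the gene of the title; the window of the first 2 Mb was chosen after the lists had been seen. ARPE-19 had 25.3 ± 0.58 peaks there and H7 had 4 ± 1 (SD, n = 3, exact permutation p = 0.1). Of 47 merged regions, 12 had a peak in 3 of 3 ARPE-19 libraries and in no H7 library, and 0 had a peak in 3 of 3 H7 libraries and in no ARPE-19 library. Over all merged regions of the genome these classes made up 26.0% and 1.82%, so the 12 of 47 were close to the share over the genome. The difference was absent when the 8622 strongest peaks of each library were taken, with a mean of 3 peaks per library in each line. With a -log10 q of at least 5 the means were 16.7 peaks in ARPE-19 and 1.33 in H7. Among the ARPE-19 regions were those from 1470018 to 1470315, with 19 to 24 summit reads, and from 1542932 to 1543205, with 15 to 25. Only 2 regions were called in both lines, from 271318 to 271822 and from 1385853 to 1386330.

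Within that window of 2 Mb, 9 of the 47 regions had an H7 peak and no ARPE-19 peak, and each of the 9 was called in 1 H7 library. Over all merged regions of the genome, 17.1% were called in 1 H7 library and in no ARPE-19 library. These 9 regions differed in strength. The one with the highest -log10 q, 11.4, lay from 1228957 to 1229278 and was called in H7 replicate 2, with 19 summit reads and an authors' fold enrichment of 8.49. Another, singled out after its values were seen, lay from 1295146 to 1295600 with its summit at 1295481. It was chosen for its position, with TERT in mind, and not for its strength, but where TERT lies on hg19 was not analysed here. It was called in H7 replicate 1, with 16 summit reads over a local background of 1.20, an authors' fold enrichment of 7.73 and a -log10 q of 9.24. No ARPE-19 peak was called between 1195048 and 1327532, a span of 132 kb that holds both regions and another of the 9, from 1229814 to 1229990. Such a gap was not particular to this place. The stretch from 957755 to 1112040 in the same window, which is longer, had no ARPE-19 peak either. A peak in 1 of 3 H7 libraries against 0 of 3 ARPE-19 libraries can only give p = 1 (Fisher's exact test, two-sided), so that test says nothing about the region. A missing peak means that the region was not called at this depth, not that its chromatin was closed.

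**Figure D3:**
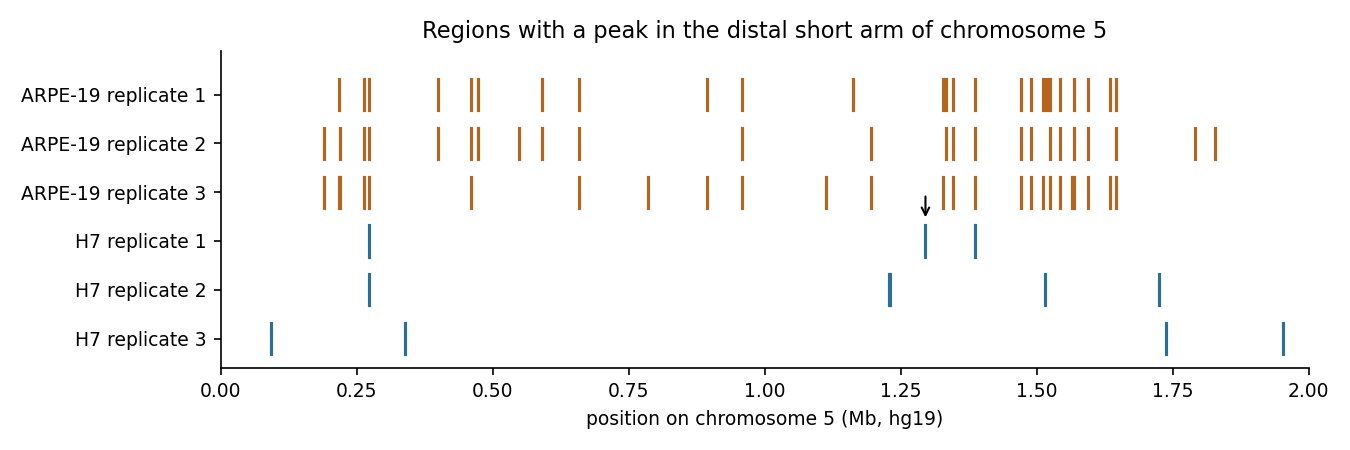
Vertical marks give the regions with a peak in each of the 6 libraries along the first 2 Mb of chromosome 5 (horizontal axis, Mb on hg19); the arrow points to the region from 1295146 to 1295600. ARPE-19 libraries have 25.3 peaks on average and H7 libraries 4, and the region at the arrow is marked in H7 replicate 1 only.

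The peaks of the 2 lines were spread differently over the autosomes, a comparison chosen after the lists had been seen. On 18 of 22 autosomes the shares of the 3 H7 libraries did not overlap those of the 3 ARPE-19 libraries, where chance gives 10% or 2.2 autosomes. The H7 share was lower on 11 and higher on 7 of these, and with the same number of peaks per library it was lower on 6 and higher on 7. The autosomes come from the same 6 libraries and their shares depend on each other, so they are not separate trials. However many autosomes are apart, the exact permutation p of this split cannot fall below 0.1. Chromosome 22 held 0.780% ± 0.062 of autosomal peaks in ARPE-19 and 0.344% ± 0.045 in H7 (SD, n = 3), a log2 ratio of -1.18. Chromosome 20 held 2.09% ± 0.0061 and 1.28% ± 0.052, a log2 ratio of -0.71, and chromosome 16 held 2.55% ± 0.023 and 1.63% ± 0.051, a log2 ratio of -0.64. Chromosome 13 held 3.34% ± 0.055 and 3.97% ± 0.29, a log2 ratio of 0.25. With the same number of peaks per library, the ratio was -0.74 on chromosome 20 and -0.56 on chromosome 16, and it was 0.0076 on chromosome 22 and 0.030 on chromosome 19, where it had been -0.51. Chromosome 15 turned from -0.13 to 0.17, with the libraries of the lines apart both times.

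**Figure D4:**
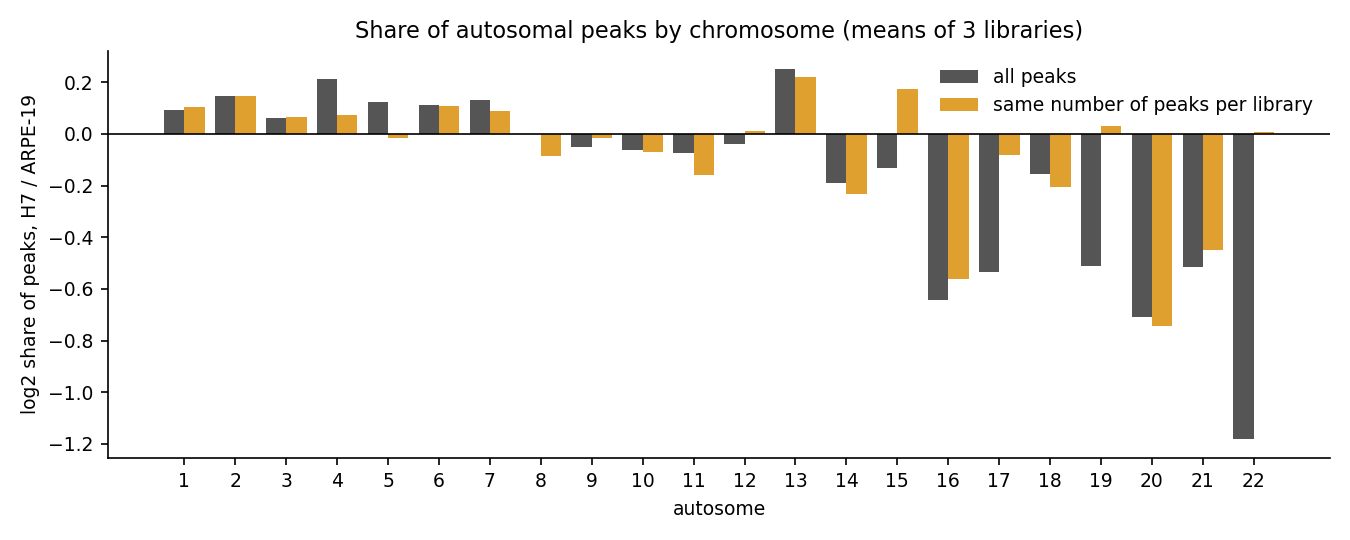
Bars give the log2 ratio of the mean share of autosomal peaks in 3 H7 libraries to that in 3 ARPE-19 libraries for each of 22 autosomes, with all peaks and with the same number of peaks per library. Chromosomes 16 and 20 are low with both, while the ratio on chromosome 22 goes from -1.18 to 0.0076.

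The regions called in one line only were also spread unevenly over the autosomes. There were 526 ARPE-19-only and 10 H7-only regions on chromosome 16 (odds ratio of H7-only against the other autosomes 0.272), 469 and 9 on chromosome 20 (odds ratio 0.275), and 265 and 1 on chromosome 19 (odds ratio 0.0542). Chromosome 13 had 737 and 72 (odds ratio 1.44). Chromosome 21, with a log2 ratio of peak shares of -0.51, had an odds ratio of 0.831 (adjusted p = 0.731, Fisher's exact test), and chromosome 3, whose peak shares overlapped between the lines, had 1.26 (adjusted p = 0.0327). By Fisher's exact test with Benjamini-Hochberg adjustment over 22 autosomes, the adjusted p was 9.2e-06 on chromosome 16, 3.33e-05 on chromosome 20, 9.2e-06 on chromosome 19 and 0.0199 on chromosome 13. In all, 10 autosomes had an adjusted p under 0.05, 6 with fewer and 4 with more H7-only regions. With the same number of peaks per library, 3 autosomes did: chromosome 16 (odds ratio 0.307, adjusted p 0.00023 by Fisher's exact test), chromosome 20 (0.381, 0.0075) and chromosome 13 (1.62, 0.0080). Chromosome 19 then had 27 ARPE-19-only and 10 H7-only regions, an odds ratio of 0.835 with an adjusted p of 0.893. These tests count regions, which are not independent replicates.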

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

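Peak numbers and covered bases kept their direction under all 12 alternatives run for each, with log2 differences of H7 from ARPE-19 from -2.79 to -1.61 and from -3.00 to -0.63. No alternative could bring their exact permutation p below 0.1. Autosomes only, one p threshold, no peaks of high local background, and all settings for the chromosome 5 window and the autosomes were chosen after the lists had been seen. With a -log10 q of at least 5 there were 605 H7-only regions, and the log2 difference in the chromosome 5 window was -3.64, where it was -2.66 with all peaks. With the same number of peaks from every library there were 4012 ARPE-19-only regions, the log2 difference in the chromosome 5 window was 0, and the log2 ratio of shares became 0.030 on chromosome 19, 0.0076 on chromosome 22, 0.17 on chromosome 15, 0.012 on chromosome 12 and -0.016 on chromosome 5, each with its sign turned. Overlap became 13.4% for H7 peaks in ARPE-19 lists and 13.3% the other way (added after the lists had been seen). That setting shortens every list except that of H7 replicate 3, and beyond the tests on chromosomes 17, 19 and 22 the cause was not tested. The ratio on chromosome 8, -0.0019 with all peaks, became 0.0029 without peaks of high local background and ranged from -0.029 to 0.047 when a library was left out; the cause was not tested. A peak in at least 2 of 3 libraries against 0 of 3 gave 4384 H7-only and 33818 ARPE-19-only regions, and against at most 1 of 3 it gave 4840 and 36430, by looser definitions. Leaving out each library in turn gave 1567 to 3087 H7-only regions, the highest without H7 replicate 3, and 22449 to 27575 ARPE-19-only regions. Overlap by 50% of both peaks, a stricter rule, lowered the mean overlap to 58.8% within ARPE-19, 31.7% within H7, 18.2% for H7 peaks in ARPE-19 lists and 5.03% for ARPE-19 peaks in H7 lists. The shares of 13 to 20 autosomes set the lines apart. The number of autosomes on which the regions of one line differed by Fisher's exact test, 10 with all peaks, was 5 with a -log10 q of at least 5, 3 with the same number of peaks and 5 with overlap by 50% of the merged region, each with fewer regions tested, and 9 to 12 when a library was left out. ARPE-19-only regions outnumbered H7-only ones in every setting run, by 2.18 to 27.2 times. With 4 to 6 summit reads at the threshold, depth limits weak peaks.

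The replicate numbers gave no clear sign of a pairing. Libraries of the same number correlated in their deviations by 0.0018, 0.0058 and 0.027, and those of different number by -0.026 to 0.017. Values this small do not exclude that libraries of the same number were handled together. With the replicate block, the log2 differences were -1.86 for peaks and -2.12 for covered bases, each with an exact sign-flip p of 0.25, the smallest that 3 pairs can give. Counting every row gave -1.86, since no interval was repeated. The same number of peaks gives no value for peaks per library. Alternatives for promoters, TERT, gene lists and motifs were not run.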

Other observations

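The tests in this part were chosen after the results had been seen, except those of summits at shared regions and of the spacing of H7-only regions. For the local background on chromosomes 16, 20 and 21 together, the rule was written before that test. Those chromosomes were picked from their peak shares, which had been seen.

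Regions of one line were dense in a few windows of 1 Mb on hg19. ARPE-19-only regions were most frequent on chromosome 3 from 177 to 178 Mb, with 30 regions, on chromosome 5 from 9 to 10 Mb, with 28, and with 27 each on chromosome 2 from 192 to 193 Mb and chromosome 9 from 75 to 76 Mb. The median was 8 in windows with at least 1 such region. H7-only regions were most frequent on chromosome 1 from 197 to 198 Mb and chromosome 6 from 134 to 135 Mb, with 6 each. Both windows also held ARPE-19-only regions, 8 and 6 of them. The next, on chromosome 1 from 209 to 210 Mb, held 5 H7-only and 19 ARPE-19-only regions. Windows on chromosome 1 starting at 74, 170, 196, 200 and 213 Mb held 4 H7-only regions each, and windows of 4 on other chromosomes were not compared. Chromosome 1 as a whole had an odds ratio of 1.07 (adjusted p = 0.655, Fisher's exact test). Crowding on a part of it, and any cause, was not tested. A hypothesis that H7-only regions cluster was tested on the 1470 autosomal ones. Of these, 9.18% had another within 50 kb, while 10000 draws of as many regions per chromosome from the regions of one line gave a mean of 9.27% (95% range 7.28% to 11.4%, one-sided permutation p = 0.536). No clustering within 50 kb beyond that of the regions of one line, of which 21378 were ARPE-19-only, was detected. The draws kept the number per chromosome and looked only at near neighbours. The test therefore cannot say whether the dense windows of 1 Mb, or longer stretches, are unusual.

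The H7 lists were shorter although the H7 libraries did not look shallower. Fewer reads would lower the genome-wide background, but per base of the smallest peak width it was 1.31 times as high in H7, and every H7 library lay above every ARPE-19 library. The background may include duplicate reads, whose treatment was not given, so fewer distinct reads in H7 stay possible. A larger share of mitochondrial reads would raise the mitochondrial background over the genome-wide one, but the ratio in H7 was 0.657 of that in ARPE-19. Weaker enrichment of open chromatin in H7 is a candidate explanation: at 1495 autosomal regions called in all 6 libraries, the median of summit reads over background was 23.5 ± 1.66 in H7 and 43.4 ± 5.29 in ARPE-19 (SD, n = 3), a ratio of 0.541. That test does not separate lower library quality from lower accessibility of the same regions in stem cells, and the difference between the cell lines was not tested apart from the libraries.

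The 10 splits of the 6 libraries are too few for a share under 0.05. The real split, the 1 split that gave as many, had 1537 H7-only and 22042 ARPE-19-only regions, and the highest count of any other split was 153.

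Of 22 autosomes, 6 had an H7 share lower by over 0.5 on the log2 scale, and each was tested by itself. If the longer ARPE-19 lists reached weaker peaks there, the difference would end with the same number of peaks per library. It went from -0.53 to -0.081 on chromosome 17, from -0.51 to 0.030 on chromosome 19 and from -1.18 to 0.0076 on chromosome 22, where the libraries of the lines then overlapped, so list length may account for these. Chromosome 22 then held only 0.27% of the autosomal peaks in each line, so its value rests on few peaks. With a -log10 q of at least 5, the difference stayed at -0.50, -0.55 and -1.57 on chromosomes 17, 19 and 22. The ARPE-19 lists also stayed longer in that setting, so it does not settle the question. With the same number of peaks, the difference went from -0.64 to -0.56 on chromosome 16, from -0.71 to -0.74 on chromosome 20 and from -0.51 to -0.45 on chromosome 21, where the lines stayed apart and list length is not the whole cause. Extra copies of these last 3 chromosomes in ARPE-19 would put the log2 local background of H7 over ARPE-19 at shared regions more than 0.3 below that of the other autosomes. On chromosome 16 it lay 0.090 above it (95% bootstrap interval over 23 regions -0.19 to 0.21), with the whole interval above -0.3. On chromosomes 20 (-0.053, interval -0.43 to 0.04, 21 regions) and 21 (-0.22, interval -0.36 to 0.03, 14 regions) the interval crossed -0.3. The local background is of the same library and can hold reads of the peaks themselves, and the intervals resample regions and not libraries. Extra copies therefore stay open for all 3 chromosomes. Over all 58 regions the value was -0.050 (95% bootstrap interval -0.19 to 0.04). By the rule written before that test, an interval above -0.3 would speak against extra copies. That value decides nothing here for the same reasons, and because the chromosomes went both ways, a condition that was not in the rule. Base composition and a difference between the cell lines were not tested.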
